A study of Mus musculus with 19 samples.

How the data were processed

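RNA from the left ventricle of 19 male C57BL/6 mice was measured on Affymetrix expression arrays with 45101 probe sets, with 1 array per mouse and no pooling. Per the labels, the mice were operated at 7 weeks of age and the tissue was taken 4 weeks later. The protocols in the labels describe freezing of the left ventricle after the atria and the right ventricle had been removed. Total RNA was purified on columns, and biotinylated cRNA was made from 3 ug of it. The labels form 3 groups: 5 sham-operated mice, 7 mice with banding of the aorta and no heart failure, and 7 mice with banding and heart failure. They do not say which criterion defined heart failure. They also give organ weights and tibia length for each mouse.

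The authors deposited log2 expression values, computed with GCRMA per the submitters' processing notes; its version is not given in the sources used here. GCRMA corrects the background of each probe by its sequence, normalises across arrays and summarises the probes of a set, so dim probe sets are drawn to a common floor and their fold changes are compressed. The deposited values ran from 2.19 to 16.77, the array medians lay between 2.85 and 2.99, and 50.5% of the values were under 3. No count or sequencing depth applies to arrays, and the number of arrays limits the precision.

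Probe sets were named through GEO's platform annotation. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were not listed there. The gene ID of 34754 of those with 1 symbol was found in the reference gene table, and 0 were renamed. No genome build is named in the sources used here, so no coordinates are given. Probe sets with log2 above 4 in at least 5 arrays were kept, which left 20497, of which 18595 had 1 symbol. Where a gene had several, as 4837 genes did, the probe set with the highest mean over all arrays stood for it, which left 10733 genes. Among genes named for their rank, for a function list or by fixed choice, none had probe sets past an unadjusted limma p of 0.05 with opposite signs. Probe sets of genes named only as markers, or after their values were seen, were not compared in this way.

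The 3 pairs of groups were compared in a single limma fit over all 19 arrays (limma 3.58.1, R 4.3.3, lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment over the 10733 genes and a threshold of 0.05. Fold changes are differences of group means of log2 values, and their errors are standard errors of the fit. The median standard error of a log2 change was 0.105 in both comparisons with sham and 0.0955 between the banded groups. Tested on simulated data in which 100 of the 10733 genes were changed by 0.5 and 100 by 1 on the log2 scale, the fit recovered 71% and 96% of them for banded mice without heart failure against sham, 69% and 95% for banded mice with heart failure against sham, and 72% and 92% between the banded groups. In these simulations 8 of 175, 5 of 169 and 6 of 170 calls were false. The simulated noise was independent between genes and held no structure beside the groups, so these rates need not hold for the real arrays.

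For gene groups, 30 lists were fixed, 17 of genes that share a function and 13 of markers of cell types or states that a heart sample could hold. Each was compared with all other tested genes by camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Of these lists 28 had at least 2 tested genes; the lymphocyte and skeletal muscle markers each had 1, so they were not tested as lists. An estimated correlation in camera, and fry, were run beside it. fry tests whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. Counts within a list use the adjustment over all genes unless they are said to be adjusted over the list alone. The lists, the tests, the filter, the first set of alternatives and the rule for named genes were set before the data were examined. By that rule the text names, in each comparison, the 3 genes with the largest rise and the 3 with the largest fall among those past the threshold, the 2 members of each function list with the largest change past it, and always Nppa, Nppb, Myh7, Myh6, Atp2a2, Col1a1, Col3a1 and Postn; members of marker lists are named where 5 or fewer passed. No fold is given for a named gene with an array below the filter in a compared group. Other genes, such as members of a list that went against the rest of it, were chosen after their values were seen.

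Organ weights were divided by tibia length. The labels give weights in mg, but the index in the labels equals 1000 times the labelled weight over tibia length in 19 of 19 mice (within 0.01), so the unit is uncertain and the index is used as given. Group means were compared by exact two-sided permutation tests (scipy 1.17.1, pandas 2.3.3, Python 3.11.15), adjusted over 9 tests. Figures were drawn with matplotlib 3.10.9.

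Alternatives chosen beforehand were no filter, a filter at log2 above 6, the mean of a gene's probe sets, every probe set tested on its own, leaving out probe sets with less specific probes, quantile normalising again, setting array medians equal, eBayes with trend and robust, array weights, only the arrays of the groups compared, the series of animal IDs (3 series) as a block, a fold change of at least 1.5, weights not divided by tibia length, and leaving out each mouse in turn. After the data were seen, a block for a set of arrays with high 18S ribosomal RNA signal, each of these array sets alone, and the mean of the atrial markers as a covariate, alone and with the block, were added, and so was the difference between the 3' and 5' actin control probe sets as a covariate. The limma, fry and permutation p-values of group comparisons measure the spread between separate mice, while camera with the preset correlation compares the genes of a list with other genes. 0 columns of the deposited table belonged to no sample. Scanner images and probe-level files were not used here.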

Results

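Gene expression in the left ventricle of adult male mice was measured 4 weeks after sham surgery or banding of the aorta, an operation that narrows the vessel and raises the pressure against which the left ventricle ejects. The series title concerns the extracellular matrix in remodelling of the ventricle with and without heart failure. Of the 19 mice, 5 were sham-operated, 7 were banded without heart failure and 7 were banded with heart failure, and each gave 1 array. The log2 signal of 44.5% to 45% of the probe sets lay above the filter on each array. A control probe set for 18S ribosomal RNA split the arrays into a set of 6 with high signal and a set of 13 with low signal. In the high set, sham mice 1 to 3 lay between 9.03 and 10.1 and banded mice without heart failure 5 to 7 between 11 and 11.8. The low set held sham mice 4 and 5 (6.25 and 7.37), banded mice without heart failure 1 to 4 (5.14 to 6.89) and all 7 mice with heart failure (5.64 to 7.62). The actin control, a sign of RNA quality, also differed between the groups. Its 3' minus 5' difference was 0.943 to 1.02 in sham mice, 0.672 to 0.898 in banded mice without and 0.661 to 0.905 with heart failure. All 14 banded mice lay below every sham mouse (exact permutation p = 0.00253 for both groups against sham, and 0.952 between the banded groups). The labels name no batch, but they give animal IDs in 3 series. All 6 mice of the high set, and no other sham mouse or banded mouse without heart failure, belong to 1 series, which also holds mice 1 and 2 with heart failure, of the low set. The block for array set was fitted in each comparison, and the low set also gave each comparison on its own.

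**Figure D1:**
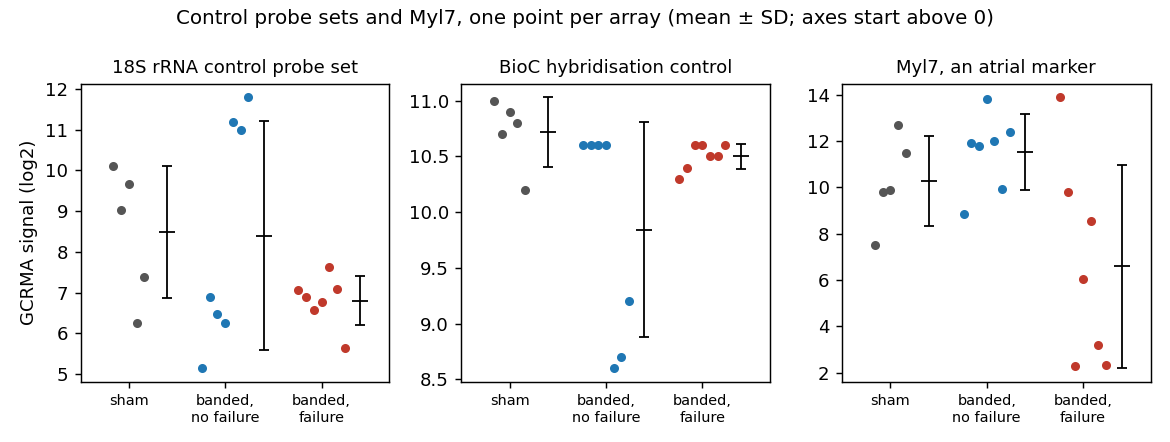
Log2 array signal of the 18S ribosomal RNA control, the BioC hybridisation control and the atrial gene Myl7, with 1 point per array, replicates from left to right and bars for mean ± SD (n = 5, 7 and 7). The 18S signal of sham mice 1 to 3 and banded mice without heart failure 5 to 7 sits at 9.03 or above, and Myl7 spans 2.3 to 13.9 among the mice with heart failure.

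Left ventricular weight over tibia length was 5.14 ± 0.261 (SD, n = 5) in sham mice, 6.98 ± 0.435 (n = 7) in banded mice without heart failure and 8.97 ± 0.607 (n = 7) in banded mice with heart failure. It was thus 35.8% and 74.5% above sham (exact permutation p = 0.00253 for each, the smallest these group sizes allow, adjusted p = 0.00325) and 28.5% higher with than without heart failure (exact permutation p = 0.000583, again the smallest possible, adjusted p = 0.00175). The lung and the right ventricle were heavier in the mice with heart failure. Lung weight over tibia length was 8.58 ± 0.492 in sham mice, 9.1 ± 0.8 without and 20.4 ± 2.19 with heart failure, and the right ventricle gave 1.39 ± 0.176, 1.33 ± 0.15 and 2.05 ± 0.247. Both differences between mice with heart failure and sham, 138% for lung and 47.5% for right ventricle, had an exact permutation p of 0.00253, and both differences between the banded groups, 124% and 54.1%, one of 0.000583. The labels do not say whether lung or right ventricular weight was part of the criterion for heart failure. If so, these differences follow from the definition of the groups and their p-values test nothing. Between banded mice without heart failure and sham, the differences of 0.513 for lung (exact permutation p = 0.205, adjusted p = 0.23) and -0.0596 for right ventricle (exact permutation p = 0.53) did not pass the threshold. Without sham mouse 4, that lung difference was 0.711 and passed it (exact permutation test, adjusted p = 0.0273). Tibia length was 17.8 ± 0.186 mm, 17.5 ± 0.238 mm and 17.6 ± 0.407 mm.

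**Figure D2:**
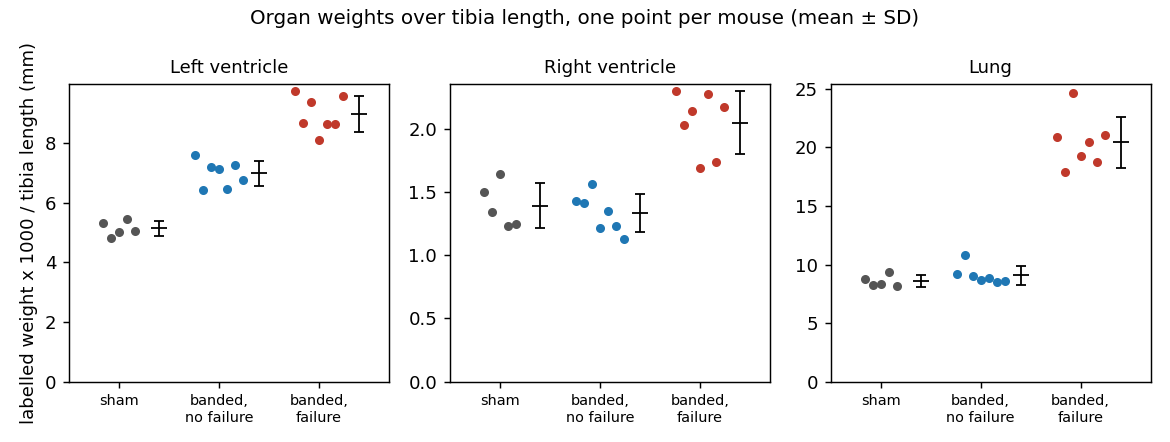
Weight of the left ventricle, right ventricle and lung over tibia length (labelled weight times 1000 per mm), with 1 point per mouse and bars for mean ± SD (n = 5, 7 and 7). Lung values of the mice with heart failure lie between 17.9 and 24.6, all above the 8.2 to 10.8 of the other mice.

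The comparison of banded mice without heart failure with sham mice asks what pressure overload changed in ventricles that had not failed. Of the lists, 11 of 12 fetal heart and hypertrophy genes, 8 of 9 fibrillar collagens and 15 of 22 basement membrane genes rose, and 10 of 25 fatty acid oxidation genes fell. With an estimated correlation the call held for the fetal genes alone of these 4 (adjusted p = 0.00202, 0.163, 0.088 and 0.088 with an estimated correlation). Myh7, the beta myosin heavy chain of the fetal rodent ventricle, rose 7.06-fold, from a log2 signal of 10.14 ± 0.48 (SD, n = 5) to 12.96 ± 0.45 (n = 7). Cilp, a matrix protein first known from cartilage, rose 7.77-fold, and Thbs4, a matricellular thrombospondin, 6.46-fold. The water channel gene Aqp4 fell from 5.45 ± 0.25 to 2.43 ± 0.3, below the filter on all 7 banded arrays, so no fold is given. Of 10733 genes, 1865 (17.4%) passed the threshold, 1164 higher and 701 lower, and 164 of them changed at least 2-fold (125 higher, 39 lower).

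Among fetal and hypertrophy genes, 11 of 12 rose (11 adjusted over the list alone; median log2 change 1.03), the only list that also passed with an estimated correlation (camera adjusted p = 1.49e-11, and adjusted p = 0.00202 with an estimated correlation). Nppa, which encodes atrial natriuretic peptide, rose by 1.92 ± 0.15 on the log2 scale (SE, adjusted p = 3.94e-07), and Nppb, the B-type peptide, by 1 ± 0.24 (adjusted p = 0.00886). Nppb was 11.74 in sham mouse 4 and at least 13.51 in the other sham mice, and without that mouse it rose by 0.63 (adjusted p = 0.000839). Myh7 had an adjusted p of 7.43e-07. Lman1l rose to 5.09 ± 0.54 from a level below the filter on all 5 sham arrays, so no fold is given. Myh6, the adult alpha myosin heavy chain, did not pass (adjusted p = 0.21); its probe set lay at the top of the signal range. Atp2a2, the calcium pump of the sarcoplasmic reticulum, differed by -0.03 ± 0.05 (adjusted p = 0.747) on its brightest probe set, and 3 of the other 5 by -0.16, -0.32 and -1.27 (each with an unadjusted limma p under the threshold). With the mean of its probe sets it differed by -0.36 (adjusted p = 0.045).

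Of 9 fibrillar and fibril-associated collagens 8 rose (8 adjusted over the list alone; median 0.99, camera adjusted p = 9.36e-06), with Col1a1 3.18-fold and Col3a1 1.65-fold higher and Col12a1 at 6.26 ± 0.75 against 4.48 ± 0.68 in sham. Of 22 basement membrane and network collagens and laminins 15 rose (17 and 1 lower adjusted over the list alone; median 0.6, camera adjusted p = 5.95e-10), led by Col8a2 (6.52 ± 1.07 against 4.38 ± 0.63 in sham) and Col8a1 (3.64-fold). On sham arrays Col12a1 lay above the filter in 3 of 5 and Col8a2 in 4 of 5, so no fold is given. Among 17 matricellular proteins, secreted proteins that bind matrix and cells, 10 rose (12 adjusted over the list alone; median 0.74, camera adjusted p = 2.54e-07), with Thbs4, Comp at 4.4-fold and Postn (periostin) at 3.79-fold. Collagen processing and crosslinking genes rose in 8 of 16 cases (11 adjusted over the list alone; camera adjusted p = 1.75e-05), with the lysyl oxidase genes Lox at 2.55-fold and Loxl3 at 2.1-fold. TGF-beta signalling and myofibroblast genes rose in 7 of 16 (8 adjusted over the list alone; camera adjusted p = 8.43e-05), with the ligands Tgfb2 at 3.58-fold and Tgfb3 at 2.15-fold. With an estimated correlation the adjusted p was 0.163 for the fibrillar collagens, the matricellular proteins, the crosslinking genes and the TGF-beta genes, and 0.088 for the basement membrane list.

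Elastic fibre and glycoprotein genes went both ways, with 10 of 18 higher and 2 lower (11 and 3 adjusted over the list alone; median 0.6, camera adjusted p = 0.00268, adjusted p = 0.324 with an estimated correlation). Ltbp2, which binds fibrillin, rose 5.92-fold, and the members that fell were Efemp1 (fibulin-3), 4.23-fold, and Emilin2, by -0.69 on the log2 scale. Integrins and matrix receptors rose in 4 of 17 (4 adjusted over the list alone; camera adjusted p = 0.00952, adjusted p = 0.163 with an estimated correlation), led by Itga9 at 2.25-fold and Itga5 at 2.19-fold. The other proteoglycans rose in 4 of 13 (5 adjusted over the list alone; camera adjusted p = 0.0385, adjusted p = 0.228 with an estimated correlation), with Cspg4 at 1.72-fold and Sdc3 at 1.54-fold. The small leucine-rich proteoglycans (4 of 12 rose, 4 adjusted over the list alone; camera adjusted p = 0.0644, fry adjusted p = 0.033) and the matrix proteases and inhibitors (4 of 20 rose, 4 adjusted over the list alone; camera adjusted p = 0.103, fry adjusted p = 0.0171) were not called as lists by camera. Their leading members were Bgn (biglycan) at 2.15-fold and Prelp at 1.64-fold, and the inhibitor Timp1 at 2.34-fold and the protease Mmp2 at 2.07-fold.

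Fatty acid oxidation genes fell in 10 of 25 cases (15 adjusted over the list alone; median -0.25, camera adjusted p = 1.87e-10, adjusted p = 0.088 with an estimated correlation). Slc25a20, the carnitine carrier of mitochondria, fell 1.57-fold and Acaa2, the thiolase of the last step of beta-oxidation, 1.51-fold. Acot1, an acyl-CoA thioesterase outside the list, fell 4.29-fold. Oxidative phosphorylation genes fell in 4 of 48 (0 adjusted over the list alone, where 20 had an unadjusted limma p under the threshold; median -0.1, camera adjusted p = 5.38e-07, adjusted p = 0.17 with an estimated correlation), with Cox8b 1.18-fold and Ndufs8 1.17-fold lower. Cardiac ion channel genes fell in 3 of 15 (5 adjusted over the list alone; median -0.32, camera adjusted p = 0.0132, adjusted p = 0.163 with an estimated correlation), among them Kcnv2 by 1.8-fold and Kcnj5 by 1.52-fold. Glycolysis genes rose in 5 of 17 (5, and 1 lower, adjusted over the list alone; camera adjusted p = 0.161, fry adjusted p = 0.017), with Pfkp 1.74-fold and Hk1 1.36-fold higher. Calcium handling genes rose in 2 and fell in 4 of 15 (5 and 5 adjusted over the list alone; camera adjusted p = 0.565), where Trdn (triadin) fell 1.51-fold and the calcium channel subunit Cacnb2 1.37-fold. Of the other 5 Trdn probe sets, 2 bright ones differed by -0.03, with an unadjusted limma p over the threshold, and 3 by -0.26 to -1.45, with one under it. Chemokines and cytokines had 1 member that rose of 16 (1 adjusted over the list alone; camera adjusted p = 0.21), Cx3cl1, 2-fold.

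Of the cell type markers, the endothelial list was called (2 of 13 rose, Robo4 and Tie1, and 3 adjusted over the list alone; median 0.25, camera adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation). Fibroblast markers rose in 5 and fell in 1 of 11 (5 and 1 adjusted over the list alone; camera adjusted p = 0.162). Of those that rose, Col15a1 and Mfap5 are also counted in the basement membrane and elastic fibre lists. For macrophage and leukocyte markers, limma called 0 of 18 (1 at an unadjusted p under the threshold; median -0.16, camera adjusted p = 0.161, fry adjusted p = 0.498). Smooth muscle and pericyte markers rose in 2, Notch3 and Pdgfrb, and fell in 1, Abcc9, of 8 (camera adjusted p = 0.179, fry adjusted p = 0.00681). Cardiomyocyte markers rose in 2 of 15, Des and Mybpc3 (camera adjusted p = 0.704), and acute phase and stress genes rose in 1, Hspb1, and fell in 2, Hspa5 and Xbp1, of 13 (camera adjusted p = 0.947). Limma called 0 of 13 cell division genes (1 at an unadjusted p under the threshold; fry adjusted p = 0.321). It called 0 of 12 immediate early genes (2 unadjusted; fry adjusted p = 0.327). The atrial markers had a median of 1.07 with 1 of 7 lower, Kcnj3 (camera adjusted p = 0.743). In the low 18S set alone the medians were 1.05 for fetal genes, 1.15 for fibrillar collagens, 1.01 for matricellular proteins, -0.38 for fatty acid oxidation, 0.08 for macrophage markers, 0.53 for fibroblast markers and -0.13 for atrial markers. In the high set alone they were 1.09, 0.77, 0.57, -0.24, -0.33, 0.01 and 1.05 in the same order. In the low set 6 fetal genes, 4 fibrillar collagens and 9 matricellular proteins rose and 6 fatty acid oxidation genes fell. Other lists kept fewer calls there: 4 basement membrane, 3 elastic fibre, 2 TGF-beta, 1 crosslinking and 1 integrin gene rose. Of oxidative phosphorylation and ion channel genes 0 and 1 fell.

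In the low 18S set alone, 4 banded mice against 2 sham mice, 343 genes passed, of which 281 were among the 1865. There 99.6% of the 1865 kept their sign, but these arrays are part of the full set, so this is no separate support. In the high set alone, 3 against 3, 1818 passed, and with the array set as a block 2351. The BioC hybridisation control was 8.6 to 9.2 in the 3 banded mice of the high set and 10.7 to 11 in its 3 sham mice. Neither count can therefore part banding from a technical difference within that set. With the actin difference as a covariate 1199 genes passed, 734 of them among the 1865. The call was lost for 15 of 42 named genes, among them Efemp1, Comp, Lox, Timp1, Itga9 and Col3a1. It was also lost for the ion channel (camera adjusted p = 0.0786), other proteoglycan (0.293) and endothelial (0.616) lists. Every banded mouse lay below every sham mouse in the actin difference, so this covariate cannot be parted from banding. Calls lost with it, here or with heart failure, cannot be laid to RNA quality. Nor can it clear any call against sham, kept or lost, of a difference in RNA quality. Without sham mouse 2 the count was 1185 and the median of the ion channels -0.21, and 5 of 42 named genes (Kcnj5, Lox, Timp1, Cox8b and Col3a1) lost their call without 1 or another mouse, with adjusted p up to 0.0989. Quantile normalising again gave 902 higher and 926 lower, and equal array medians 844 and 1081, so the balance of directions depends on the scaling.

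**Figure D3:**
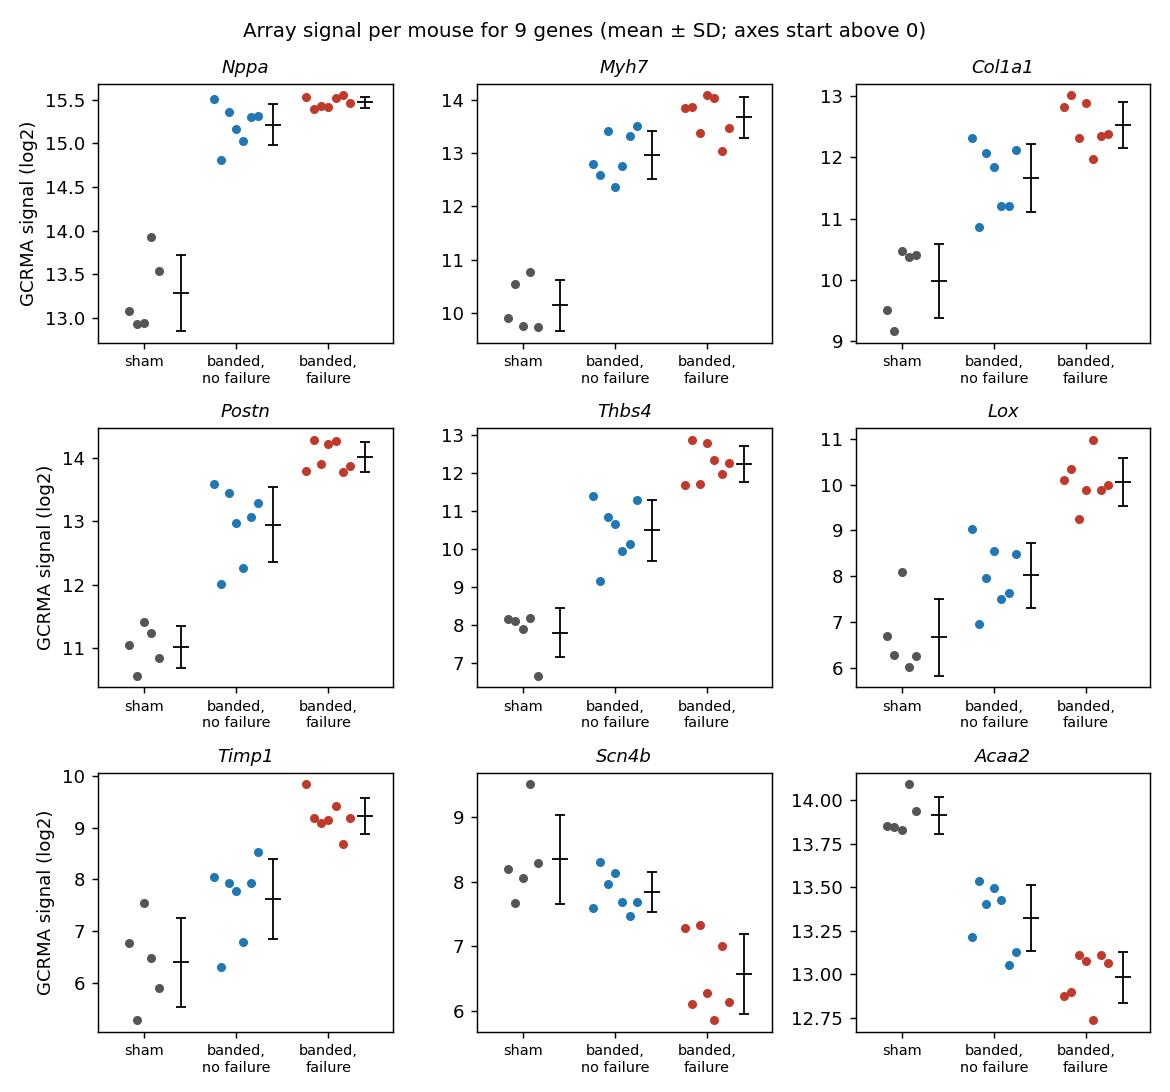
Log2 array signal of 9 named genes, with 1 point per mouse and bars for mean ± SD (n = 5, 7 and 7). Every banded mouse lies above every sham mouse for Nppa, Myh7, Col1a1, Postn and Thbs4, and every mouse with heart failure lies above every other mouse for Lox and Timp1.

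Banded mice with heart failure were compared with sham mice to describe the failing ventricle. Of the lists, 11 of 12 fetal heart genes, 16 of 16 collagen processing genes and 12 of 13 cell division genes rose, and 38 of 48 oxidative phosphorylation genes and 10 of 15 cardiac ion channel genes fell. Their adjusted p was 0.00751, 0.0552, 0.358, 0.0552 and 0.0552 with an estimated correlation, and 5 cell division genes rose with the array-set block and 2 in the low 18S set. Thbs4 rose 21.6-fold, from 7.79 ± 0.64 (SD, n = 5) to 12.22 ± 0.48 (n = 7), Cilp 19.8-fold and Ltbp2 19.7-fold. The largest falls were Aqp4 (from 5.45 to 2.24, below the filter on all 7 arrays), Efemp1 (from 7.94 to 5.03, below it on 1) and Ces1d, a carboxylesterase of lipid metabolism (7.02-fold). In total 4220 genes (39.3%) passed, 2193 higher and 2027 lower, and 553 changed at least 2-fold, 401 of them upward and 152 downward.

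Fetal and hypertrophy genes rose in 11 of 12 (11 adjusted over the list alone; median 1.23, camera adjusted p = 1.68e-09), again the only list past the threshold with an estimated correlation (adjusted p = 0.00751 with an estimated correlation). Myh7 rose by 3.52 ± 0.24 on the log2 scale (SE, adjusted p = 1.13e-08), Nppa by 2.18 ± 0.15 (adjusted p = 1.13e-08) and Nppb by 1.11 ± 0.24 (adjusted p = 0.00151). Without sham mouse 4, Nppb rose by 0.74. Myh6 passed on a probe set at the top of the signal range (-0.15 ± 0.05, adjusted p = 0.0231), but its other probe set differed by 0.14 (unadjusted limma p over the threshold), so no direction is given. The Myh6 call was lost with the array-set block (adjusted p = 0.124) and without sham mouse 1 or 2. Atp2a2 differed by -0.12 ± 0.05 on its brightest probe set (adjusted p = 0.0642), and the other 5 differed by -0.11 to -1.1 (each with an unadjusted limma p under the threshold). With the mean of its probe sets it differed by -0.4 (adjusted p = 0.0131).

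Collagens and the enzymes that process them rose almost throughout. Of 9 fibrillar and fibril-associated collagens 8 rose (9 adjusted over the list alone; median 1.86, camera adjusted p = 1.44e-07, adjusted p = 0.0903 with an estimated correlation), with Col1a1 5.81-fold and Col3a1 2.51-fold higher and Col12a1 at 8.04 ± 0.49. All 16 collagen processing and crosslinking genes rose (16 adjusted over the list alone; median 0.71, camera adjusted p = 5.17e-09), led by Lox at 10.5-fold and Loxl3 at 4.39-fold. Of 22 basement membrane and network genes 20 rose and 1, Lama5, fell (20 and 1 adjusted over the list alone; median 0.81, camera adjusted p = 2.53e-10), with Col8a2 at 8.19 ± 1.01 and Col8a1 6.68-fold higher. Matricellular proteins rose in 14 of 17 (14 adjusted over the list alone; median 1.07, camera adjusted p = 4.2e-09), with Comp at 15.9-fold and Postn at 7.94-fold. With an estimated correlation the adjusted p was 0.0552 for the crosslinking, basement membrane and matricellular lists.

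Further matrix lists were called too. Elastic fibre and glycoprotein genes rose in 13 and fell in 2 of 18 (13 and 3 adjusted over the list alone; camera adjusted p = 4.36e-05, adjusted p = 0.143 with an estimated correlation), with Mfap4 7.51-fold higher and Efemp1 and Emilin2 lower. TGF-beta signalling and myofibroblast genes rose in 11 of 16 (11 adjusted over the list alone; camera adjusted p = 2.86e-05, adjusted p = 0.091 with an estimated correlation), with Tgfb2 at 7.29-fold and Tgfb3 at 3.48-fold. The small leucine-rich proteoglycans rose in 7 of 12 (7 adjusted over the list alone; camera adjusted p = 0.000965, adjusted p = 0.208 with an estimated correlation), with Fmod (fibromodulin) at 7.81-fold and Bgn at 3.65-fold. Integrins and matrix receptors rose in 8 of 17 (8, and 1 lower, adjusted over the list alone; camera adjusted p = 0.00307, adjusted p = 0.102 with an estimated correlation), with Itga9 at 3.56-fold and Itgb5 at 2.1-fold. Matrix proteases and inhibitors rose in 7 of 20 (5 adjusted over the list alone; camera adjusted p = 0.00572), with Timp1 at 7.12-fold and Mmp2 at 3.63-fold. Other proteoglycans rose in 8 and fell in 1, Gpc4, of 13 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0122), with Prg4 (lubricin) 2.77-fold and Vcan (versican) 2.58-fold higher; for both of these lists the adjusted p was 0.143 with an estimated correlation.

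Of 48 oxidative phosphorylation genes 38 fell (39 adjusted over the list alone; median -0.24, camera adjusted p = 2.82e-12), among them Ndufs4, a subunit of complex I, 1.42-fold. Cox7c passed on a probe set near the floor (3.36 ± 0.71 with heart failure, 6 of 7 arrays below the filter, against 4.47 ± 0.58 in sham), so no fold is given, and that call was lost with the array-set block (adjusted p = 0.0544). Fatty acid oxidation genes fell in 19 of 25 (19 adjusted over the list alone; median -0.43, camera adjusted p = 9.57e-10), with Ucp3 2.03-fold and Acaa2 1.91-fold lower. Cardiac ion channel genes fell in 10 of 15 (10 adjusted over the list alone; median -0.55, camera adjusted p = 4.78e-05), with the sodium channel subunit Scn4b 3.43-fold lower and Kcnv2 at 3.94 against 5.23 in sham, with 4 of 7 arrays above the filter. For these 3 lists the adjusted p was 0.0552 with an estimated correlation. Glycolysis genes rose in 5 and fell in 4 of 17 (5 and 4 adjusted over the list alone; camera adjusted p = 0.483), with Pfkp 2.53-fold and Hk1 1.47-fold higher. Calcium handling genes rose in 3 and fell in 5 of 15 (3 and 6 adjusted over the list alone; camera adjusted p = 0.472, fry adjusted p = 0.0147; median 0.05 but mean -0.01), with Trdn 1.74-fold lower. Itpr2, an inositol trisphosphate receptor, was 2.09-fold higher on 1 of 6 probe sets, at 1.07 on the log2 scale. A nearly as bright one gave 0.17 (unadjusted limma p over the threshold), and the tested one gave 0.44 with the array-set block and 0.32 with the actin covariate (adjusted p = 0.044 and 0.491). Chemokines and cytokines rose in 3 and fell in 3 of 16 (3 and 3 adjusted over the list alone; camera adjusted p = 0.486), with Cx3cl1 2.87-fold higher and Ccl6 2.74-fold lower.

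Cell division genes rose in 12 of 13 (12 adjusted over the list alone; median 0.87, camera adjusted p = 0.000462, adjusted p = 0.358 with an estimated correlation). Fibroblast markers rose in 7 and fell in 2 of 11, with Scara5 and Clec3b lower (7 and 2 adjusted over the list alone; camera adjusted p = 0.0202, adjusted p = 0.358 with an estimated correlation). Col15a1 and Mfap5, which rose, are again also counted in those matrix lists. Macrophage and leukocyte markers had a median of -0.07 and 1 of 18 that rose, Cx3cr1 (0 adjusted over the list alone, 3 at an unadjusted limma p under the threshold; camera adjusted p = 0.658). Endothelial markers rose in 4 of 13, Esam, Pecam1, Robo4 and Tie1 (camera adjusted p = 0.183, fry adjusted p = 0.0147). With the array-set block, and in the low 18S set, limma called 0 of the 13. Cardiomyocyte markers rose in 2, Des and Mybpc3, and fell in 2, Ckm and Tnni3, of 15 (camera adjusted p = 0.509), with Myh6 past the threshold but given no direction. Smooth muscle and pericyte markers rose in 1, Pdgfrb, and fell in 2, Abcc9 and Kcnj8, of 8 (camera adjusted p = 0.897). Acute phase and stress genes rose in 6 and fell in 2 of 13 (camera adjusted p = 0.282). With the array-set block 3 of them rose and 1 fell, and in the low 18S set 2 rose and 0 fell. Immediate early genes rose in 2 of 12, Atf3 and Egr2 (camera adjusted p = 0.286). Atrial markers had a median of -1.56, with Dkk3 higher and Kcnj3 and Stk39 lower of 7 (camera adjusted p = 0.282). Mylpf, the 1 skeletal muscle marker tested, passed at -0.42 ± 0.15 (adjusted p = 0.0317). The call rested on sham mice 2 and 3 (5.27 and 5.69), as the other 3 sham mice and 3 mice with heart failure shared the value 4.56, and it was lost without either (adjusted p = 0.104 and 0.0964), without mouse 1 or 7 with heart failure (0.0522 and 0.0518) and with the array-set block (0.196). All 7 arrays with heart failure lay in the low 18S set, and against the 2 sham mice of that set the medians were 1.84 for fibrillar collagens, 1.42 for matricellular proteins, -0.54 for fatty acid oxidation, -0.21 for oxidative phosphorylation, 0.28 for macrophage markers, of which 5 rose, and 0.93 for cell division genes. With the array-set block the macrophage median was 0.19. Limma called 25 of 48 oxidative phosphorylation genes lower in the low set and 38 with the block. It called 4 of 13 other proteoglycans, 14 of 22 basement membrane genes and 12 of 16 crosslinking genes higher in the low set.

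Within the low set 2670 genes passed, 2156 of them among the 4220, and 98.9% of the 4220 kept their sign. These arrays are part of the full set, so the shared sign is no separate support. With the block 3611 passed, 2949 of them shared, and with the actin covariate 2705, 2233 of them shared. With that covariate Itpr2, Prg4, Ucp3, Cox7c, Myh6 and the other proteoglycan list (adjusted p = 0.0616) lost their call. Without mouse 1 with heart failure the medians of the proteases and the integrins were 0.29 and 0.14. Of 43 named genes 3 changed their call without 1 mouse: Ucp3 (without sham mouse 4), Myh6 (without sham mouse 1 or 2) and Atp2a2 (without sham mouse 5 or mouse 7 with heart failure). The balance of 2193 higher to 2027 lower became 1794 to 2586 after quantile normalising again and 1683 to 2774 with equal array medians.

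**Figure D4:**
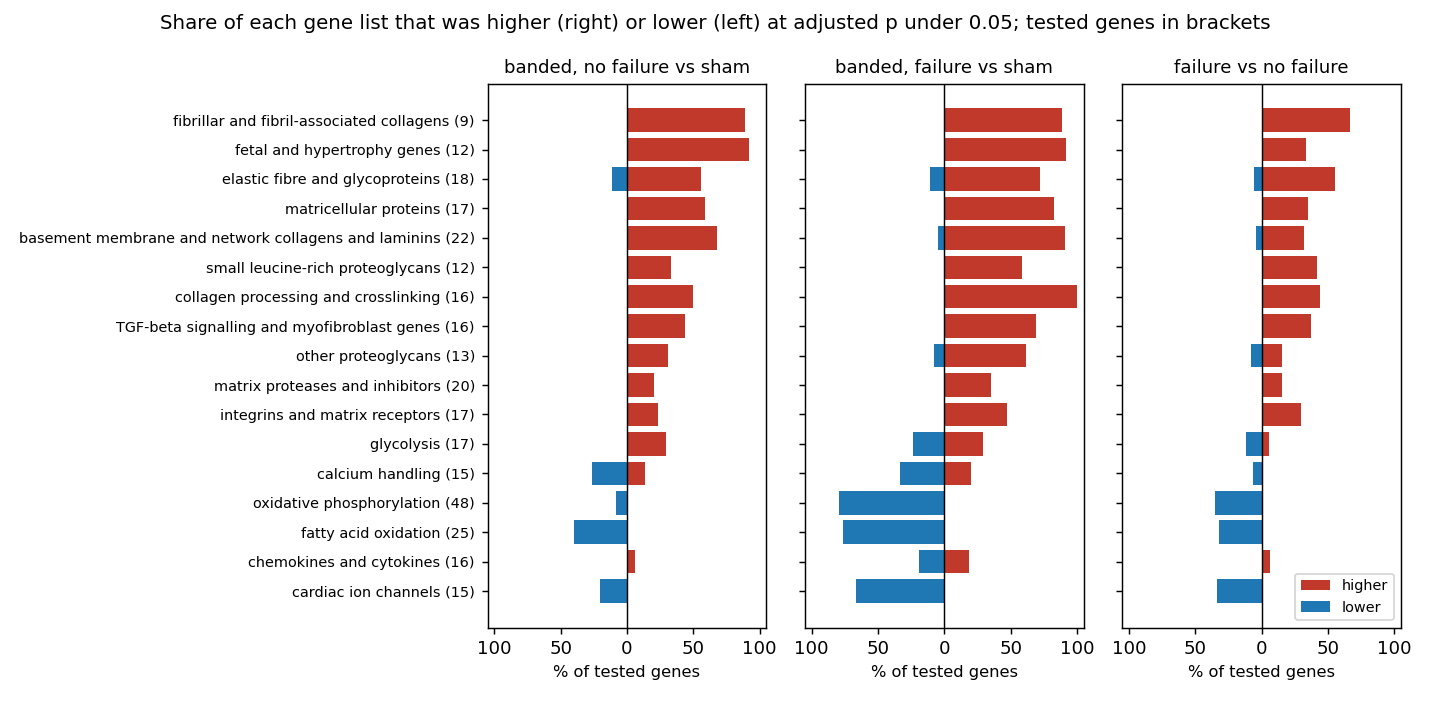
Share of the tested genes of each function list (number in brackets) that were higher or lower at an adjusted limma p under 0.05, in % of the list, for the 3 comparisons. Collagen processing reaches 16 of 16 higher and oxidative phosphorylation 38 of 48 lower in the mice with heart failure against sham.

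The comparison of banded mice with and without heart failure asks what differed between the banded groups. Left ventricular weight over tibia length also separated them fully, at 8.09 to 9.75 with and 6.42 to 7.59 without heart failure. Heart failure can therefore not be parted here from the degree of hypertrophy. Of the lists, 6 of 9 fibrillar collagens, 7 of 16 collagen processing genes and 6 of 17 matricellular proteins rose, and 17 of 48 oxidative phosphorylation, 8 of 25 fatty acid oxidation and 5 of 15 cardiac ion channel genes fell. All 6 lists were called by camera with the preset correlation and none with an estimated one (adjusted p = 0.177 with an estimated correlation for fatty acid oxidation and 0.0989 for the other 5). Lox, which crosslinks collagen and elastin, rose 4.13-fold, from 8.01 ± 0.71 (SD, n = 7) to 10.06 ± 0.52 (n = 7), and Cthrc1, a secreted protein with a collagen repeat, from 4.88 ± 1.36, with 4 of 7 arrays above the filter, to 6.98. Chodl (chondrolectin) rose to 5.39 ± 0.96 from 3.51 ± 0.45, where 1 of 7 arrays lay above the filter, so no fold is given for either. The natriuretic peptides did not pass the threshold (Nppa 0.26 ± 0.13, adjusted p = 0.237; Nppb 0.11 ± 0.22, adjusted p = 0.806). The threshold was passed by 1017 genes (9.48%), 411 higher and 606 lower, with 63 changed at least 2-fold (52 higher, 11 lower).

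Crosslinking genes rose in 7 of 16 (10 adjusted over the list alone; median 0.39, camera adjusted p = 2.97e-09), with Lox and Loxl3 (2.09-fold) in front. Matricellular proteins rose in 6 of 17 (11 adjusted over the list alone; median 0.82, camera adjusted p = 6.68e-08), with Comp 3.62-fold, Thbs4 3.34-fold and Postn 2.09-fold higher. Fibrillar collagens rose in 6 of 9 (8 adjusted over the list alone; median 0.86, camera adjusted p = 1.03e-07), among them Col12a1 at 3.43-fold, Col1a2 at 1.91-fold and Col1a1 at 1.83-fold, while Col3a1 at 0.6 ± 0.2 missed the threshold (adjusted p = 0.0586). Basement membrane and network genes rose in 7 and fell in 1, Lama5, of 22 (13 and 1 adjusted over the list alone; median 0.29, camera adjusted p = 2.2e-07), with Col8a2 at 3.18-fold and Col8a1 at 1.84-fold. For each of these 4 lists the adjusted p was 0.0989 with an estimated correlation. Elastic fibre genes rose in 10 of 18, and Emilin2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 2.79e-06). The small leucine-rich proteoglycans rose in 5 of 12 (7 adjusted over the list alone; camera adjusted p = 1.95e-05). Matrix proteases and inhibitors rose in 3 of 20 (5 adjusted over the list alone; camera adjusted p = 0.00147). The leading members of these lists were Ltbp2 at 3.33-fold and Mfap4 at 2.56-fold, Fmod at 3.49-fold and Bgn at 1.69-fold, and Timp1 at 3.05-fold and Mmp2 at 1.75-fold. Each of these 3 lists had an adjusted p = 0.116 with an estimated correlation.

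TGF-beta signalling and myofibroblast genes rose in 6 of 16 (6 adjusted over the list alone; camera adjusted p = 0.0016), with Tgfb2 at 2.04-fold and Fstl1 at 1.66-fold. Integrins and matrix receptors rose in 5 of 17 (6 adjusted over the list alone; camera adjusted p = 0.0189), with Cd44 at 1.44-fold and Itgb5 at 1.4-fold; both lists had an adjusted p = 0.178 with an estimated correlation. Other proteoglycans rose in 2, Vcan (1.64-fold) and Gpc6 (1.37-fold), and fell in 1, Gpc1, of 13 (5 and 1 adjusted over the list alone; camera adjusted p = 0.03, fry adjusted p = 0.0722, adjusted p = 0.19 with an estimated correlation), a call lost with the array-set block. Fetal and hypertrophy genes rose in 4 of 12 (4, and 1 lower, adjusted over the list alone; median 0.2, camera adjusted p = 0.000933, adjusted p = 0.0989 with an estimated correlation). Uchl1, a ubiquitin hydrolase, was 2.21-fold and Myh7 1.63-fold higher, the latter at an adjusted p of 0.049. With the array-set block Myh7 (adjusted p = 0.0566), Col8a2 (0.0646), Cx3cl1 (0.109) and Col1a1 (0.117) lost their call. Cx3cl1 was the 1 of 16 chemokines and cytokines that rose (2, and 1 lower, adjusted over the list alone; 1.43-fold; camera adjusted p = 0.718).

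Oxidative phosphorylation genes fell in 17 of 48 (31 adjusted over the list alone; median -0.15, camera adjusted p = 2.72e-11, adjusted p = 0.0989 with an estimated correlation), with Ndufs4 1.24-fold and Cox7a1 1.21-fold lower. Fatty acid oxidation genes fell in 8 of 25 (11 adjusted over the list alone; median -0.16, camera adjusted p = 2.67e-05, adjusted p = 0.177 with an estimated correlation), with Mlycd, which removes malonyl-CoA, 1.39-fold and Acot2 1.34-fold lower. Ces1d, outside the list, fell 2.71-fold. Cardiac ion channel genes fell in 5 of 15 (7 adjusted over the list alone; median -0.37, camera adjusted p = 5.87e-05, adjusted p = 0.0989 with an estimated correlation), with Scn4b 2.4-fold and the potassium channel Kcnd2 1.6-fold lower. Calcium handling had 1 member that fell of 15, Hrc, which binds calcium in the sarcoplasmic reticulum, 1.26-fold (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.318, fry adjusted p = 0.0411). Glycolysis had Pfkp 1.45-fold higher and Slc2a4, the insulin-regulated glucose transporter, and Ldhb lower of 17 (1 and 5 adjusted over the list alone; Slc2a4 1.27-fold; camera adjusted p = 0.714). Myh6 and Atp2a2 differed by -0.06 ± 0.04 and -0.1 ± 0.05 (adjusted p = 0.462 and 0.21).

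The largest fall was that of Myl7, the atrial myosin light chain (11.52 ± 1.62 without and 6.59 ± 4.4 with heart failure, where 4 of 7 arrays lay above the filter), followed by the hepcidin gene Hamp (6.79 ± 1.73 and 4.16 ± 0.8, 3 of 7 above the filter), so no fold is given for either. Atrial markers fell in 3 of 7, Myl7, Kcnj3 and Stk39 (5 adjusted over the list alone; median -0.8, camera adjusted p = 0.00708, adjusted p = 0.198 with an estimated correlation). With the mean of these 7 markers as a covariate, which cannot test Myl7 as it is part of that mean, Hamp differed by -1.35 (adjusted p = 0.155), and 1011 genes passed, 726 of them among the 1017. Col8a2, Vcan, Cd44, Acot2, Pfkp and Slc2a4 also lost their call with it. With this covariate and the array-set block together, 15 of 44 named genes lost their call: Col1a1, Col1a2, Col8a2, Comp, Postn, Fmod, Vcan, Fstl1, Cx3cl1, Kcnd2, Ces1d, Acot2, Pfkp, Hamp and, by construction, Myl7. Cell division genes rose in 1 of 13, Mcm6 (5 adjusted over the list alone; median 0.51, camera adjusted p = 1.04e-05, adjusted p = 0.192 with an estimated correlation). With the array-set block 0 of the 13 passed, and in the low 18S set 0 had even an unadjusted limma p under the threshold. Fibroblast markers rose in 3 of 11, Mfap5, Pi16 and Gsn (4, and 1 lower, adjusted over the list alone; camera adjusted p = 0.00768, adjusted p = 0.21 with an estimated correlation). Mfap5 is also counted in the elastic fibre list. Acute phase and stress genes were called as a list (median 0.25, camera adjusted p = 0.0189, fry adjusted p = 0.0732, adjusted p = 0.192 with an estimated correlation) with 0 of 13 called by limma (4 at an unadjusted p under the threshold; 0 adjusted over the list alone). Cardiomyocyte markers fell in 2 of 15, Ckm and Tnni3, smooth muscle and pericyte markers in 2 of 8, Abcc9 and Kcnj8, and endothelial markers in 1 of 13, Cdh5, while Egr2 was the 1 of 12 immediate early genes that rose (camera adjusted p = 0.0892, 0.084, 0.449 and 0.419; fry adjusted p = 0.0399, 0.00485, 0.196 and 0.705). For the 2 adipocyte and the 2 erythroid markers limma called 0 in each comparison, also without adjustment, and fry gave adjusted p = 0.987 and 0.555 here. Macrophage and leukocyte markers were called in 0 of 18 by limma (1 at an unadjusted p under the threshold; median 0.09, camera adjusted p = 0.318, fry adjusted p = 0.705). Camera with an estimated correlation called 0 of the 28 lists in this comparison (10 at an unadjusted p under the threshold), camera with the preset correlation 18 and fry 19.

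In the low 18S set alone, with 7 mice against 4, 149 genes passed, 128 of them among the 1017. All 1017 kept their sign there (r = 0.985 between the log2 changes, from arrays that are part of the full set), and 30 of 44 named genes lost their call, while 17 of 18 called lists kept theirs by camera with the preset correlation. Few members passed there: by limma 1 fibrillar collagen, 0 matricellular proteins, 3 crosslinking genes and 0 small leucine-rich proteoglycans rose (8, 9, 8 and 6 at an unadjusted p under the threshold). Of oxidative phosphorylation, fatty acid oxidation and ion channel genes, limma called 0, 4 and 1 lower (22, 14 and 8 unadjusted). The medians there were 0.7 for fibrillar collagens, 0.49 for matricellular proteins, 0.31 for crosslinking genes, -0.12 for oxidative phosphorylation and -0.35 for ion channels. The block for array set gave 957 genes, 650 of them shared. The count rested on single mice, with 508 without banded mouse 5 without heart failure, 672 without mouse 6 of that group and 599 without mouse 2 with heart failure, and array weights raised it to 1914. Leaving out 1 mouse changed the call of 11 of 44 named genes: Myl7, Myh7, Cx3cl1, Vcan, Slc2a4, Col8a2, Col1a1, Col3a1, Cd44, Fstl1 and Acot2, with adjusted p between 0.00709 and 0.136. Without mouse 5 with heart failure the medians of the other proteoglycans and the acute phase genes were 0.11 and 0.1 (camera adjusted p = 0.164 and 0.136). Without mouse 1 those of the integrins, proteases and TGF-beta genes were 0.06, 0.1 and 0.15 (camera adjusted p = 0.0547, 0.0103 and 0.00819). Quantile normalising again gave 379 higher and 688 lower, and equal array medians 367 and 729.

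The changes in both banded groups against sham overlapped. Of the genes called by limma, 973 were higher in both, 653 lower in both and 0 opposite. The same 5 sham arrays served both comparisons. In 20 splits with no sham array in both, a median of 326 genes were higher in both (136 to 468; 59.3 for unrelated calls) and 201 lower in both (69 to 341; 30.5 for unrelated calls). In opposite directions went 0 to 42 (87.9 for unrelated calls). Across the 10733 genes, which are not independent replicates, the log2 changes of the banded groups correlated at r = 0.874. Unchanged groups simulated against shared sham arrays gave r = 0.583 on average, and sham arrays split between the comparisons gave a median of 0.709 (0.459 to 0.77 over 20 splits). The covariance was 0.142 against 0.0136 simulated, a difference of 0.128, and 0.127 with the sham arrays split. A further 1220 genes were called higher and 1374 lower against sham with heart failure and not without it, and for 216 and 332 of these the difference between the banded groups passed in the same direction.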

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

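The tests of array runs, time of day, atrial tissue and re-expression, and the tests of mouse 5 with heart failure, were chosen only after the result was seen; the regroupings of the animals were chosen before. Of 246 groups of values tested, 19 held a mouse far from the others of its group, where chance alone gives about 12.3 at 1 in 20 groups. The values tested included S100a8, Lcn2 and Fkbp5, which had been seen before, so these counts are no fair test of an excess. In each case what stood out was the gap between the highest or lowest mouse and its nearest neighbour. Mouse 5 with heart failure accounts for 6 of the 19, S100a8 and Lcn2 among them, and sham mouse 4 for 3.

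Regrouping the animals was used to ask whether chance could give as many changed genes. In each of the 3 comparisons 1 of 100 splits, the real one, gave as many. Chance is thus unlikely but not excluded, as only 100 of 792, 792 and 1716 possible splits were drawn. The splits cannot part the groups from the array sets, which are unevenly spread over them. Nor can they part banding from the actin difference in the comparisons with sham. The real counts and the highest other splits were 1865 and 1043 for banded mice without heart failure against sham, 4220 and 2112 for mice with heart failure against sham, and 1017 and 402 between the banded groups. The split with 1043 genes placed 91.7% of its animals as the 18S array sets do, so the samples hold a structure beside the groups. For the splits with 2112 and 402 genes this share was 83.3% and 71.4%. The real groups of these comparisons have the same shares, so these values show no structure beside the groups. Both splits kept 6 of the 7 mice with heart failure together, so they hold much of the real contrast. The block for array set gave 2351, 3611 and 957 genes in the 3 comparisons.

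The arrays of sham mice 1 to 3 and of banded mice without heart failure 5 to 7 differed from the others of their groups in 18S signal. A different labelling or hybridisation run would separate the control probe sets: 11 of 18 had separate ranges in the banded group (1.03 expected by chance, largest difference 2.04), and 7 of 18 in the sham group (3.6 expected), so a run is a candidate explanation for the first and stays undecided for the second. A different time of day of collection would move clock genes: the clock score differed by 1.61 between the parts (exact permutation p = 0.0286), with 9 of 10 clock genes in the direction of their arm and Nr1d1 against it, while banded mouse 2 without heart failure, in the low part, had the highest score of all (1.49). All 6 mice belong to 1 of the 3 series of animal IDs, and no other mouse of their groups does, but 2 mice with heart failure of that series lie in the low set. Run, time of day and a cohort of animals cannot be parted here, since the labels give neither run nor time, and no other biological explanation was tested.

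Myl7 ranged from 2.3 to 13.9 between arrays. If atrial tissue had been carried into some samples, other atrial genes would follow it: the mean of 5 such genes correlated with Myl7 within groups at r = 0.741 (permutation p = 0.00056; Spearman rho 0.605, p = 0.0104; r = 0.581 without the 2 farthest arrays), so carried-over tissue may explain it, although the atria had been removed per the labels. Of the 5, Cacna2d2 (r = 0.79) and Dkk3 (0.718) followed Myl7, and Myl1 (0.099), Nr2f1 (-0.0777) and Stk39 (-0.291) did not. Dkk3 and Stk39 are also in the fixed list of atrial markers. Re-expression in the loaded ventricle would raise Myl7 above sham, but it differed by -3.69 with heart failure (exact permutation p = 0.107), which leaves a group difference open. The sham mice, which were not banded, already ranged from 7.53 to 12.7. That range argues against re-expression under load as the source of the spread among sham mice.

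Mouse 5 with heart failure had 569 genes more than 2-fold from the mean of the other 6 (57 to 97 for each of the others). Degraded RNA would raise the actin 3' minus 5' difference, and it ranked 7 of 7 (0.661 against 0.716 to 0.905), which argues against degradation. Neutrophils in the tissue may contribute: 5 of 11 neutrophil genes (Ngp, Mmp8, Mmp9, Csf3r and Clec4d) were over log2 4 and highest in this mouse (13.9% of all genes), while Camp, Ltf, Mpo, Elane and Cd177 stayed at the floor. A glucocorticoid response may contribute too, with 6 of 8 responsive genes highest in this mouse (22.7% of all genes); with 1 mouse, picked because it stood apart, neither has a test between animals. Its S100a8 was 11.77 (nearest 6.131), its Lcn2 12.61 (6.63), Col8a2 6.143 (8.049), Itpr2 8.631 (7.955), Prg4 12.5 (10.66) and Fstl1 12.65 (13.12).

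Further values far from the rest of their group were spread over other mice, and no explanation was tested for them. In sham mouse 4, Nppb was 11.74 (nearest 13.51), Cx3cl1 7.147 (6.738) and Gpc6 8.557 (8.34). In sham mouse 3, Kcnv2 was 4.339 (5.327) and Lcn2 10.21 (6.697), and in sham mouse 5, Thbs4 was 6.66 (7.877) and Cox7a1 15.06 (14.87). Among banded mice without heart failure, Efemp1 was 4.402 in mouse 1 (5.568), Kcnv2 4.707 in mouse 5 (4.392), and the lung weight over tibia length 10.83 in mouse 2 (9.186). Among mice with heart failure, Efemp1 was 7.438 in mouse 1 (5.412), Trdn 12.1 in mouse 7 (12.28), and Aqp4 2.193 in mouse 3 (2.243), at the floor of the scale.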

How the results depend on the processing

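The 18S array sets, alone and as a block, and the atrial and actin covariates were chosen only after the result was seen; the other alternatives were chosen before. Testing every probe set gave 6949 calls for heart failure against sham, as more features were tested, and array weights gave 1914 between the banded groups; the cause was not tested. A fold change of at least 1.5 left 539, 1431 and 253 genes in the order of the report, by construction. An estimated correlation left 1, 1 and 0 called lists. The low 18S set left 343, 2670 and 149 genes, and the actin covariate 1199 and 2705 against sham; the cause was not tested. In the low set, of 129 named results 75 kept direction and call, 53 lost the call and 1 reversed. Of the other alternatives for named genes, the block for array set kept 123 of 129, the atrial covariate, which holds Myl7 itself, 117, both together 112, and the actin covariate 109. The mean of a gene's probe sets kept 115 and no filter 117. Of 47 called lists, all 47 kept their call under both scalings, with no filter and with the higher filter, 46 with the array-set block, 43 with the actin covariate and 42 with array weights. The correlation of the banded groups was 0.823 with the atrial covariate and 0.824 with covariate and block; the cause was not tested. Myh6 between banded mice without heart failure and sham reversed to 0.03758 with the mean of its probe sets (adjusted p = 0.84) and to 0.006851 in the low set (adjusted p = 0.974), and Nppb between the banded groups to -0.1792 with the atrial covariate (adjusted p = 0.676); none of these passed the threshold. Leaving out 1 mouse gave 1185 (without sham mouse 2) to 2200 genes (without sham mouse 4), 3538 to 4388, and 508 (without banded mouse 5 without heart failure) to 1146 (without mouse 1 of that group). For banded mice without heart failure against sham, the lung difference ranged from 0.224 to 0.711 (without sham mouse 4, exact permutation test, adjusted p = 0.0273) and that of the right ventricle from -0.0996 to 0.00295 (without sham mouse 3, exact permutation test, adjusted p = 0.982). Signal over background limits dim genes: 50.5% of the values lay under 3.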

Other observations

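The relations below were chosen before the result was seen, so no test in this part was chosen after it. Whether collagen or metabolic gene levels follow hypertrophy between animals of 1 group was asked within each banded group. The left ventricular weight index correlated with the mean level of fibrillar collagens at r = 0.636 in the 7 banded mice without heart failure (exact permutation p = 0.131, adjusted p = 0.378; Spearman rho 0.643, r = -0.0962 without the 2 farthest mice). In the 7 mice with heart failure it was r = -0.25 (exact permutation p = 0.565, adjusted p = 0.565; Spearman rho 0, r = -0.563 without the 2 farthest). With the mean level of fatty acid oxidation genes, r was -0.513 without heart failure (exact permutation p = 0.241, adjusted p = 0.378; Spearman rho -0.571, r = -0.0938 without the 2 farthest) and -0.486 with heart failure (exact permutation p = 0.283, adjusted p = 0.378; Spearman rho -0.536, r = -0.198 without the 2 farthest). None of the 4 relations passed the threshold. By the rule set beforehand, r of 0.5 or less for collagens, or of -0.5 or more for fatty acid oxidation, counted against a relation. Both values with heart failure, -0.25 and -0.486, met it. With 7 mice the 95% limits of r still reach past these bounds, so none of the 4 relations is excluded. They ran from -0.225 to 0.939 and from -0.844 to 0.62 for collagens without and with heart failure. For fatty acid oxidation they ran from -0.913 to 0.391 and from -0.907 to 0.422.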
